A study of Mus musculus with 16 samples.

How the data were processed

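RNA sequencing counts of lavage cells were available for 16 libraries: 4 from saline males, 4 from saline females, 4 from bleomycin males and 4 from bleomycin females, all taken on day 14. The labels name no batch, litter or pair, the replicate codes are not shared between groups, and each library was taken as 1 biological replicate.

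Per the submitters' processing notes, the authors used fastp 0.12.2, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 (no version given), and name the builds mm9 and mm10 without a role for each. The gene coordinates in the deposited tables are those of GRCm38 (mm10): 54409 of the 54532 gene identifiers are in GENCODE M21, and 53499 of these (98.33%) have identical coordinates there. The table of counts was made by the authors as raw counts per Ensembl gene, with no normalization. The FPKM table was also made by the authors, and its values equal the counts divided by the gene length and by a constant per library (largest relative spread 1.027e-14), whose definition is not stated. The log2 fold changes and the p-values in the 5 deposited comparison tables come from the authors' own comparisons, and those tables list only genes with an unadjusted p up to 0.04998. The 16 count columns were matched to the samples by the codes in their names, with 0 columns left over.

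The counts were the main measurement. Total counts per library were 18.07 ± 2.256 (saline females), 18.06 ± 1.175 (saline males), 21.16 ± 2.464 (bleomycin females) and 22.96 ± 1.444 (bleomycin males) in units of 1e+06 counts, mean ± SD with n = 4. At this depth 3 counts over the 4 libraries of a group, the floor used for lower bounds, correspond to 0.0386, 0.0385, 0.0376 and 0.0355 CPM in the same order. Genes were kept with edgeR's filterByExpr by group (minimum count 10), which left 15257 of 54532. TMM factors from edgeR ran from 1.053 to 1.098 in saline and from 0.8633 to 1.027 in bleomycin libraries. CPM of single genes in the text are divided by the total times this factor. The list levels, the summed haemoglobin genes, the strict filter and the gene-by-gene comparison of C49 and C50 with C33 use the library total alone. For 203 entries several genes share a symbol, and these were kept apart by identifier.

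One model with 1 coefficient per group was fitted to all 16 libraries in edgeR 4.0.16 (quasi-likelihood F test) under R 4.3.3, so that the groups share one estimate of the spread. It gave 6 comparisons: bleomycin against saline in males, in females and averaged over the sexes, male against female under saline and under bleomycin, and the interaction of bleomycin with sex. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p below 0.05. The fold changes of the sexes were set against each other by Pearson and Spearman correlation and orthogonal regression across genes, without a p-value. Replicates were compared by a chi-square per gene on genes with at least 20 counts in the pair, and the principal components used log2 CPM with a prior count of 2.

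There were 31 gene lists with 449 symbols, of which 17 symbols stand in more than 1 list: markers of resident alveolar macrophages, monocytes and monocyte-derived macrophages, neutrophils, T cells, NK and cytotoxic lymphocytes, B and plasma cells, eosinophils, mast cells and basophils, dendritic cells, epithelial cells, fibroblasts and endothelium, and red blood cells, and genes of fibrosis-associated macrophages, alternative activation, complement, matrix proteases, lysosomes, cholesterol biosynthesis, fatty acid oxidation, fatty acid synthesis and storage, glycolysis, NRF2, interferon response, MHC class II, cytokines, p53, the immediate early and heat shock response, proliferation, mitochondrial transcripts, steroid receptors, the Y chromosome and X escape. The lists were written from general knowledge, and their members were counted as risen or fallen over all genes and adjusted over the list alone. Members that failed the filter on low counts were left out, and the numbers of members in the text are of those that passed. Genes absent under saline passed it through the bleomycin groups alone, so that their rise was largely set by the filter. Lists were tested with camera (limma 3.58.1, on voom values, with the correlation estimated per list). The level of a list in a library is the mean of log2(CPM + 1) over its measured members, with CPM by library total and no composition scaling. Levels were compared by an exact permutation test of 4 against 4 libraries (70 arrangements, smallest p 0.0286).

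The genes named in the text follow a rule. For each comparison they are the 10 largest rises and 10 largest falls among genes that passed, have a symbol and a protein-coding biotype (predicted models left out), have at least 10 CPM in the higher group, and do not overlap between the groups compared (no such condition for the interaction). To these were added the 4 members of each described list with the smallest p, the members at its top and bottom by fold change, and the Y-linked genes, Xist and the genes that escape X inactivation as a check of the sex labels. Some genes that the rule selects are not reported here. Samples, comparisons, tests, lists, this rule and the settings below were fixed before the data were examined.

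The other settings tried were DESeq2's size factors in edgeR, the Wald test of DESeq2 1.42.0, limma voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with an FPKM of at least 1 in 4 libraries, no filter on low counts, a strict filter (10 CPM in 4 libraries), only the 8 libraries compared, leaving out the 3 bleomycin libraries whose codes lie outside the run of the others (C33, C49 and C50), leaving out X and Y genes, an adjusted p below 0.01, a change of at least 2-fold, and leaving out each library in turn. For lists they were camera with a preset correlation of 0.01, fry, and lists without shared members, and for list levels a pseudocount of 0.1, FPKM and the median member. Chosen after the data were seen were a model with the code run as a term and a fit without composition scaling. Other splits of the libraries into groups of the same sizes, all 35 or a draw of 100, were fitted for each comparison.

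The procedure was tested on simulated data with the 15257 genes and the group sizes of the study, in which 200 genes were changed. In the averaged comparison 77.6% of 1.5-fold, 89.6% of 2-fold and 100% of 4-fold changes were recovered, under saline between the sexes 46.3, 76.1 and 98.5%, and for the interaction 29.9, 61.2 and 86.4%, with 0 in the wrong direction. Of the genes called, unchanged genes made up 6.49% for bleomycin in males, 4.85% in females, 5.82% in the average, 2.65% and 3.66% between the sexes under saline and bleomycin and 3.28% for the interaction. Camera called the raised list and 0 of 50 unchanged lists in the comparison of males. In the simulation few genes changed, up or down at random, and genes varied independently of each other. The changed genes were drawn above a minimum mean CPM, so that recovery of genes with fewer counts was not tested. Before the change, the groups compared were given a common mean for each gene. In the data 43.9 to 63.6% of the genes were called for bleomycin, and list members varied together. The simulated rates therefore need not hold for the bleomycin comparisons, nor the camera result for the real lists. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. The authors' FPKM were used in the alternatives alone, and the per-library values repeated in the deposited comparison tables were not used here.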

Results

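RNA was measured by sequencing in cells washed from the airways (bronchoalveolar lavage) of C57BL/6 mice aged 8 to 10 weeks, 14 days after saline or bleomycin had been placed in the oropharynx. Bleomycin is a DNA-damaging drug that injures the lung and is widely used to model pulmonary fibrosis in mice, and the dose here was 4 U per kg of body weight. Males and females received each treatment, which gave 4 groups of 4 libraries. The counts assigned to genes totalled 16385784 to 21393539 per library in saline females and 16471022 to 19207944 in saline males. Under bleomycin they totalled 18871879 to 24567609 in females and 21240382 to 24225885 in males. The design asks what bleomycin changed in the lavage cells, whether the sexes differed under each treatment, and whether the bleomycin effect depended on sex. Levels of genes below are CPM, the counts of a gene scaled to a common library total and for composition, as mean ± SD with n = 4 libraries per group. Levels of gene lists are scaled to the library total alone. Changes are log2 fold changes from the edgeR model, unless another unit is named. Their standard error (SE) is approximate, since edgeR's test gives none. It was taken as the size of the change divided by the square root of the F statistic. For genes with few counts in a group it is the least certain. Lavage cells are a mixture, so the level of a marker gene is a level of RNA and not a number of cells.

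The genes that differ with the sex chromosomes were examined first, as a check of the labels. Xist, the RNA that coats the inactive X chromosome, stood at 729 ± 59.6 CPM in saline females and 461 ± 264 CPM in bleomycin females, while no male library held more than 4 of its counts. The Y-linked Ddx3y stood at 89.2 ± 4.35 CPM in saline males and 80.8 ± 3.54 CPM in bleomycin males, Eif2s3y at 68.5 ± 4.99 and 80.4 ± 5.49 CPM, Kdm5d at 43.0 ± 1.86 and 31.3 ± 3.66 CPM, and Uty at 30.3 ± 1.96 and 26.9 ± 1.89 CPM. Eif2s3y, Kdm5d and Uty had 0 counts in all 8 female libraries, and Ddx3y had 2 counts in 1 saline female library (C76) and 0 in the other 7. These 5 genes matched the sex label of every library.

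Bleomycin and saline libraries were far apart from each other. The first principal component of log2 CPM held 78.4% of the variance and placed the bleomycin libraries between -107.7 and -66.77 and the saline libraries between 76.14 and 92.49. The second component held 5.7% and ran within the bleomycin groups, from 56.12 in C49 to -49.34 in C69 in females and from 20.85 in C33 to -14.98 in C65 in males. The saline males lay between 9.94 and 17.8 on it and the saline females between -23.42 and -1.408. On the third component, with 2.49% of the variance, all 8 male libraries were above 0 and all 8 female libraries below 0. Replicates differed by more than the sampling of reads in every group, with a chi-square per gene of 4.497 for the closest pair (C70 and C73, saline males) and 70.55 for the most distant (C49 and C69, bleomycin females), so that no library repeated another. Saline replicates lay closer together than bleomycin replicates: over 8896 genes the median SD of log2 CPM was 0.093 in saline females and 0.0947 in saline males against 0.178 in bleomycin females and 0.137 in bleomycin males. The 10 most abundant genes took 7.387 to 8.367% of the counts in saline libraries and 11.82 to 15.41% in bleomycin libraries.

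**Figure D1:**
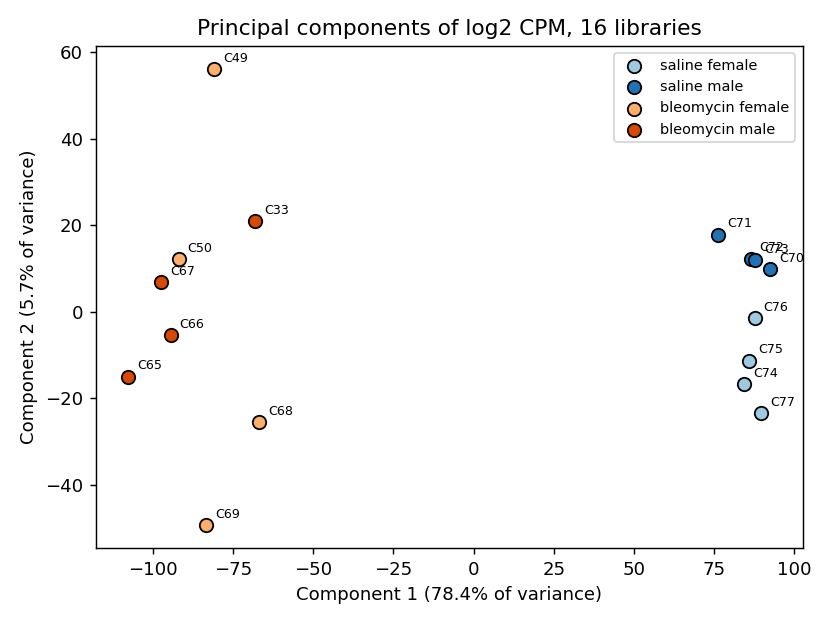
First and second principal components of log2 CPM in the 16 libraries, with one point per library, coloured by group and named by its replicate code; the axes give the component scores and the percent of variance. The bleomycin libraries lie at or below -66.77 and the saline libraries at or above 76.14 on component 1, and C49 and C69 are the ends of component 2.

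Bleomycin raised genes of monocyte-derived and scar-associated macrophages in both sexes and lowered genes that mark resident alveolar macrophages. Spp1, which encodes the secreted matrix protein osteopontin, rose from 339.8 ± 61.7 to 15104 ± 1688 CPM in males and from 357 ± 44.3 to 12121 ± 2719 CPM in females, a change of 5.28 (SE 0.14) averaged over the sexes. C1qb, a chain of the complement component C1q, rose by 8.09 (SE 0.18), Apoe, the lipid carrier apolipoprotein E, by 6.12 (SE 0.17), and the membrane-bound matrix protease gene Mmp14 by 6.84 (SE 0.15). In the other direction Fabp1, a fatty acid binding protein, stood at 97.21 ± 17.97 CPM in saline males and 2.26 ± 0.963 CPM in bleomycin males, and at 103 ± 18.2 and 3.28 ± 0.815 CPM in the females. Its change of -5.20 (SE 0.17) was accompanied by falls of -4.41 (SE 0.24) in the keratin gene Krt79, -3.01 (SE 0.17) in the ribonuclease gene Ear1 and -2.79 (SE 0.19) in the lipid droplet gene Cidec. On GRCm38 the protein-coding gene Spp1 (ENSMUSG00000029304) lies on chromosome 5, 104435118 to 104441050, C1qb (ENSMUSG00000036905) on chromosome 4, 136880129 to 136886187, and Fabp1 (ENSMUSG00000054422) on chromosome 6, 71199827 to 71205023.

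In the average over the sexes, 9700 of the 15257 genes tested passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, of which 5300 rose and 4400 fell, and 3573 changed at least 2-fold (2362 up, 1211 down). The edgeR adjusted p was 6.8e-16 for Spp1, 1.84e-16 for C1qb and 1.29e-14 for Fabp1, and in each of these genes all 8 bleomycin libraries lay on the same side of all 8 saline libraries. With library totals alone in place of composition scaling, the median change over all genes moved from 0.0116 to -0.20, 10721 genes passed, and 34.7% of them rose, against 54.6% with scaling. Small changes are therefore relative to the scaling. Among the genes with the largest fitted rises in the average were Ly6c2, Cmah, Cd38, Pou2af1, Cd79b, Lef1, Fcmr, Pax5 and Nsg2, and their levels are given with each sex below.

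**Figure D2:**
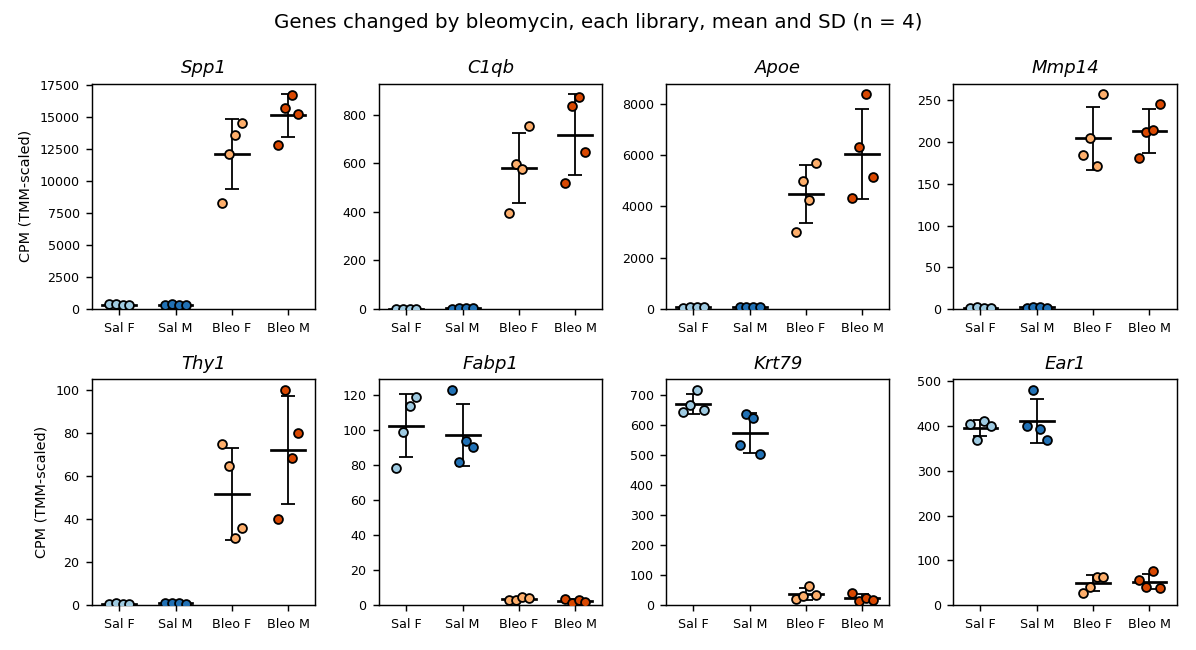
Composition-scaled CPM of 8 genes in each library (points), with the mean (long bar) and SD (error bars, n = 4) of the saline female, saline male, bleomycin female and bleomycin male groups, on linear axes that start at 0. Spp1, C1qb, Apoe, Mmp14 and the T cell marker Thy1 were higher in all bleomycin libraries, and Fabp1, Krt79 and Ear1 were lower in all of them.

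Among 20 markers of resident alveolar macrophages, 16 fell and 1 rose. The member that rose was the transcription factor gene Bhlhe41, at 0.50 (SE 0.094), and the falls were led by Fabp1, Krt79, Ear1 and Cidec, given above. Of 16 markers of monocytes and monocyte-derived macrophages, 15 rose, among them C1qa at 7.49 (SE 0.17), and Cd14 did not pass at 0.22 (SE 0.10). Ly6c2, a surface protein of classical monocytes, had 0 counts in saline females and 23.1 ± 5.60 CPM in bleomycin females, at least 597-fold higher than the floor of 3 counts over the group. Of 16 genes reported in macrophages of fibrotic lung, 13 rose and 0 fell. They included Trem2, a lipid-sensing receptor, at 3.20 (SE 0.094, 48.1 ± 6.04 to 442 ± 58.7 CPM in males), the protease inhibitor Timp2 at 2.46 (SE 0.075) and Arg1, the arginine-degrading enzyme arginase 1, at 7.12 (SE 0.39), while the tetraspanin gene Cd9 stood at -0.09 (SE 0.085) and did not pass. The list of alternative activation genes had 10 rises, including Mgl2 at 3.91 (SE 0.17) and Ccl22 at 1.98 (SE 0.14), and 1 fall among 12 members, Mrc1, the mannose receptor, at -0.71 (SE 0.083). With an estimated correlation, camera's adjusted p was 0.22 for the resident markers, 0.16 for the monocyte-derived markers, 0.16 for the fibrosis-associated genes and 0.165 for alternative activation, so none of these lists was called against the other genes.

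Most complement genes, matrix proteases and lysosome genes rose as well. Of 13 complement genes 10 rose, among them the receptor gene C3ar1 at 5.56 (SE 0.14), and 2 fell, with C5ar1 at -0.63 (SE 0.13). Of 15 matrix proteases and inhibitors 12 rose, among them Adam8 at 5.09 (SE 0.15) and Mmp12, the macrophage elastase, at 5.24 (SE 0.21, 11.2 ± 5.61 to 381 ± 57.4 CPM in females), and 1 fell, the urokinase receptor gene Plaur at -0.68 (SE 0.096). All 21 lysosome genes rose, with the cholesterol transporter gene Npc1 lowest at 0.24 (SE 0.052) and the cathepsin genes Ctsb at 1.99 (SE 0.071) and Ctsl at 1.93 (SE 0.092). Psap, the precursor of the saposins, was among the most abundant of them and rose from 5209 ± 416 to 16251 ± 1669 CPM in males. Adjusted over the list alone, 11 complement genes rose and 2 proteases fell, and the counts of every other list in the averaged comparison were the same as over all genes. The camera adjusted p was 0.165 for complement genes, 0.16 for the proteases and 0.165 for the lysosome genes with an estimated correlation.

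Lymphocyte markers, which were low under saline, and dendritic cell markers were raised: 2 of the 20 T cell markers stood at 1 CPM or more in both saline groups and 20 in both bleomycin groups. All 20 T cell markers rose, for instance Thy1, a surface glycoprotein of T cells, from 0.758 ± 0.244 to 72.2 ± 25.2 CPM in males and from 0.479 ± 0.219 to 51.5 ± 21.5 CPM in females (6.64, SE 0.29). Others were the interleukin 7 receptor gene Il7r at 5.24 (SE 0.24), the costimulatory receptor gene Icos at 6.56 (SE 0.27) and Foxp3, the transcription factor of regulatory T cells, at 2.69 (SE 0.24). Ctla4 had 0 counts in both saline groups and was at least 180-fold higher in bleomycin males and at least 155-fold higher in bleomycin females. All 10 measured NK and cytotoxic lymphocyte markers, of 12 listed, rose, with the chemokine gene Ccl5 at 5.90 (SE 0.26) and the activating receptor gene Klrk1 at 4.68 (SE 0.23). All 12 B cell and plasma cell markers rose, although 1 of them, Cd22, was slightly below 0 without composition scaling and did not pass there. They included the immunoglobulin heavy chain gene Ighm at 7.53 (SE 0.41) and the receptor component gene Cd79a at 7.31 (SE 0.48). Of 15 dendritic cell markers 14 rose, among them the growth factor receptor gene Flt3 at 3.99 (SE 0.16), the integrin gene Itgae at 3.41 (SE 0.10) and the actin-bundling gene Fscn1 at 4.92 (SE 0.23), and Batf3 stood at -0.21 (SE 0.19) and did not pass. Camera's adjusted p with an estimated correlation was 0.275 for T cells, 0.165 for NK cells, 0.309 for B cells and 0.16 for dendritic cells. These levels varied strongly between bleomycin animals: the mean log2(CPM + 1) of the T cell markers ran from 3.624 (C68) to 5.178 (C49) in bleomycin females and from 3.979 (C33) to 5.143 (C65) in bleomycin males, against 0.3697 to 0.6698 over the saline libraries.

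Markers of other cell types went both ways. The filter on low counts left 12 of 16 neutrophil and 3 of 13 eosinophil, mast cell and basophil genes. It left 5 of 14 fibroblast and endothelial and 5 of 8 red blood cell genes. Genes absent under saline passed it through the bleomycin groups alone. Of 12 neutrophil markers 9 rose, including the calprotectin subunit gene S100a8 at 4.12 (SE 0.19) and the chemokine receptor gene Cxcr2 at 2.93 (SE 0.12), and 2 fell, including Trem1 at -0.77 (SE 0.12). All 3 measured genes of the eosinophil, mast cell and basophil list rose, but their levels stayed low, with Ccr3 at 2.05 ± 1.63 CPM in bleomycin females. Of 18 epithelial markers 12 rose, with the keratin genes Krt8 at 4.62 (SE 0.14) and Krt18 at 4.51 (SE 0.21), and 3 fell, among them the adhesion gene Epcam at -2.66 (SE 0.11). Of the 5 measured fibroblast and endothelial markers 4 rose, with the smooth muscle actin gene Acta2 at 1.36 (SE 0.20), and Vwf did not pass at 0.17 (SE 0.10). The collagen gene Col1a1 had 0 counts under saline and was at least 23.7-fold higher in bleomycin males and at least 14.3-fold higher in bleomycin females, at a level of 0.913 ± 0.614 CPM in the males. All 5 red blood cell genes rose in the average, with the heme synthesis gene Alas2 at 2.67 (SE 0.64), but their spread was wide. All 5 passed in males (median change 5.11), while in females edgeR called 0 of 5 (median 1.68, unadjusted p of at least 0.11), and 3 of 5 without a low-count filter. The exact permutation p of the list level was 0.0571 in males and 0.171 in females, and limma voom called 3 of 5 in the average. The haemoglobin genes together held 5346 CPM in C65 and 61.55 CPM in C33 (scaled to the library total alone), both bleomycin males. The near-identical haemoglobin copies cannot be told apart with certainty. With an estimated correlation the camera adjusted p was 0.241 for neutrophil, 0.22 for eosinophil, 0.329 for epithelial, 0.16 for fibroblast and endothelial and 0.617 for red blood cell genes.

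Genes of lipid, sugar and redox metabolism changed as well. All 20 cholesterol biosynthesis genes rose (19 without composition scaling), from 0.41 (SE 0.071) in Mvd to 1.62 (SE 0.099) in Idi1, with the synthase gene Hmgcs1 at 1.13 (SE 0.07) and the desaturase gene Sc5d at 1.56 (SE 0.091). Of 16 genes of fatty acid synthesis and storage 7 rose, led by the desaturase genes Fads2 at 4.06 (SE 0.20), Fads1 at 2.65 (SE 0.10), Scd1 at 2.40 (SE 0.088) and Scd2 at 1.34 (SE 0.075), and 6 fell, including Lpin1 at -1.12 (SE 0.11). In this list the median change was -0.0322 although camera's direction was up, and without composition scaling 5 members rose and 9 fell. Of 18 fatty acid oxidation genes 8 fell, among them Cpt1a, which controls the entry of fatty acids into mitochondria, at -0.79 (SE 0.067), Acadvl at -0.64 (SE 0.076) and Acadm at -0.56 (SE 0.058), and 2 rose, with Acadl at 0.53 (SE 0.074). Glycolysis had 11 rises and 1 fall among 15 genes, with rises in the glucose transporter gene Slc2a1 at 1.66 (SE 0.071), the phosphofructokinase gene Pfkl at 1.36 (SE 0.065) and Hk1 at 1.25 (SE 0.073). Gapdh, whose many pseudogenes can share its reads, did not pass at -0.88 (SE 0.68). All 13 NRF2 antioxidant genes rose with composition scaling, and without it 12 rose and G6pdx was slightly below 0 and did not pass. Among them were Srxn1 at 1.25 (SE 0.089), Me1 at 3.27 (SE 0.24) and Gclc, the catalytic subunit of glutathione synthesis, at 0.69 (SE 0.064). Of 12 mitochondrially encoded genes 11 rose, with mt-Nd6 at 1.12 (SE 0.094) and mt-Co1 at 0.77 (SE 0.072). The mitochondrial share of all counts was 1.469 ± 0.140% in saline males, 1.62 ± 0.107% in saline females, 2.06 ± 0.127% in bleomycin females and 2.3 ± 0.053% in bleomycin males. Camera's adjusted p with an estimated correlation was 0.167 for cholesterol biosynthesis, 0.743 for fatty acid synthesis, 0.512 for fatty acid oxidation, 0.241 for glycolysis, 0.22 for NRF2 genes and 0.165 for the mitochondrially encoded genes.

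Interferon-stimulated genes rose without exception among the 26 measured members. Oas3, an antiviral oligoadenylate synthetase, went from 1.53 ± 0.163 to 31.9 ± 0.320 CPM in males and from 1.63 ± 0.490 to 35.3 ± 1.30 CPM in females (4.41, SE 0.10). The transcription factor gene Irf7 rose by 3.61 (SE 0.12), Oasl2 by 4.77 (SE 0.18) and Stat2 by 0.46 (SE 0.074). Of 10 genes of MHC class II presentation 9 rose, with H2-Eb1 at 2.79 (SE 0.13) and H2-Aa at 2.19 (SE 0.13), and 1 fell, H2-DMa at -0.39 (SE 0.095). Among 15 cytokine and chemokine genes 11 rose, including the macrophage growth factor gene Csf1 at 4.24 (SE 0.14), Il12b at 3.55 (SE 0.17) and the monocyte attractant gene Ccl2 at 4.90 (SE 0.39), and 1 fell, the inflammasome gene Nlrp3 at -0.99 (SE 0.10). Of 17 p53 target genes 14 rose, with the stress cytokine gene Gdf15 at 2.26 (SE 0.18), Trp53inp1 at 1.42 (SE 0.078) and Mdm2, the negative regulator of p53, at 0.69 (SE 0.061), and 1 fell, Btg2 at -0.56 (SE 0.091). In the immediate early and heat shock list 5 of 12 rose, including Egr1 at 2.93 (SE 0.21) and Junb at 1.27 (SE 0.073), and 3 fell, including Dusp1 at -0.89 (SE 0.20), while without composition scaling 4 rose and 4 fell. Of 24 proliferation genes 8 fell (17 without composition scaling), among them Mki67 at -0.48 (SE 0.095) and Mcm7 at -0.42 (SE 0.059), and 1 rose, Ube2c at 0.49 (SE 0.11). Of 5 steroid hormone receptor genes 2 rose, among them the oestrogen receptor gene Esr1 at 4.96 (SE 0.36), and Nr3c1 at -0.46 (SE 0.052) and Nr3c2 at -1.43 (SE 0.15) were the 2 that fell. With an estimated correlation the camera adjusted p was 0.059 for interferon-stimulated genes, 0.22 for MHC class II, 0.266 for cytokines, 0.165 for p53 targets, 0.548 for the immediate early list, 0.696 for proliferation and 0.772 for steroid receptors.

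No list was called by camera with an estimated correlation in the averaged comparison (smallest adjusted p 0.059). That test allows for members of a list that vary together between libraries. With the preset correlation of 0.01 the count was 24 of 31 lists, and with fry, which asks whether a list's genes move one way without reference to the other genes, it was 28. The edgeR p-values of single genes rest on the spread between libraries, each made from the lavage cells of its own sample, and not on the number of reads. Those of camera also depend on the other genes, on the size of the list and on the correlation used. For T cells camera's adjusted p was 0.275 with the estimated correlation of 0.857 and 5.59e-07 with the preset one. The exact permutation test of the list levels has 70 arrangements of 4 against 4 libraries, so that its smallest p is 0.0286, and most lists reached it in the bleomycin comparison of each sex.

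In males alone, several of the genes with the largest rises under the naming rule had few or no counts under saline. Cd79b, Pax5, the B cell transcription factor, Pou2af1, Fcmr and Cmah had 0 counts in saline males. They stood at 21.2 ± 12.6, 13.5 ± 6.16, 23.3 ± 12.6, 15.04 ± 7.902 and 25.3 ± 9.06 CPM in bleomycin males, at least 551-fold, 350-fold, 605-fold, 390-fold and 655-fold higher than the floor of 3 counts over the group. Ly6c2, Lef1, Nsg2 and Cd38 went from 1 or 2 counts in the whole saline male group to 32.3 ± 10.4, 33.5 ± 20.2, 19.0 ± 9.26 and 17.4 ± 8.52 CPM. The largest falls were in Dnah11, a gene for a dynein heavy chain, from 93.3 ± 17.6 to 1.23 ± 1.16 CPM (-6.19, SE 0.42), Fabp1 (-5.41, SE 0.24), Krt79 (-4.62, SE 0.35) and the coronin gene Coro6 (-4.47, SE 0.31). Next came Tppp (-4.27, SE 0.42), the peroxisomal thiolase gene Acaa1b (from 209.8 ± 21.7 to 13.1 ± 2.63 CPM), Cpne5 (-3.88, SE 0.21), Dtna (-3.87, SE 0.29), the potassium channel gene Kcnh4 (-3.72, SE 0.23) and the integrin gene Itgad (-3.69, SE 0.18). In all, 8614 genes passed an edgeR adjusted p of 0.05 (4810 up, 3804 down), 9355 had an unadjusted p under 0.05, and the groups did not overlap in 54.4% of the genes tested, where chance gives 2.86%. Leaving out any 1 of the 8 libraries gave 7737 (without C65) to 8927 (without C33) genes.

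In females alone, several of the largest rises also started from few or no counts. Ly6c2 and Cd38, an ectoenzyme of activated leukocytes, had 0 counts in saline females and were at least 597-fold and 311-fold higher under bleomycin. Cd8a, the co-receptor of cytotoxic T cells, rose by 8.91 (SE 0.62) to 27.7 ± 13.8 CPM and Igfbp4 by 9.05 (SE 0.68). Gimap6, Lef1, Cmah, Fam169b and Cd8b1 went from 1 to 3 counts in the whole saline female group to 31.8 ± 18.4, 21.5 ± 11.6, 26.7 ± 24.8, 10.53 ± 7.71 and 17.3 ± 5.84 CPM. The falls were led by Dnah11 (-5.04, SE 0.40), Fabp1 (-4.98, SE 0.23), Krt79 (-4.20, SE 0.34), Itgad (-4.13, SE 0.19), and Acaa1b (-3.98, SE 0.20), followed by Kcnh4 (-3.67, SE 0.22), Coro6 (-3.56, SE 0.30), Cpne5 (-3.55, SE 0.20), Tppp (-3.48, SE 0.40) and the defensin-like gene Spag11b (-3.41, SE 0.23). In all, 6699 genes passed an edgeR adjusted p of 0.05 (4070 up, 2629 down), 7693 had an unadjusted p under 0.05, and the groups did not overlap in 39.1% of the genes tested. The interferon-stimulated list was called in females (camera adjusted p = 0.0124 with an estimated correlation) and not in males (0.0641), which does not show that the sexes differed. Without C33, C49 and C50, the 3 bleomycin libraries whose code numbers lie apart from the rest, no list was called in females.

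The bleomycin changes of the sexes were close to each other. Of the genes called in either sex 5892 were called in both, 2722 in males alone and 807 in females alone, and 5889 of the shared ones had the same direction. The 3 exceptions, named after their values were seen, were the stress-induced chaperone genes Hspa1a (-1.37, SE 0.37, in males and 1.70, SE 0.42, in females) and Hspa1b (-1.32, SE 0.33, and 1.09, SE 0.36), a near-identical pair whose reads may be split uncertainly, and Rpap3 (0.29, SE 0.12, and -0.36, SE 0.12). EdgeR's test of the difference gave them an adjusted p of 0.265, 0.323 and 0.479. Across the 15257 genes, which are not independent replicates, the changes in males and females had a Pearson r of 0.946, a Spearman rho of 0.883 and a slope of 0.955 for females on males. The comparisons used separate saline groups, so no control library was shared.

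**Figure D3:**
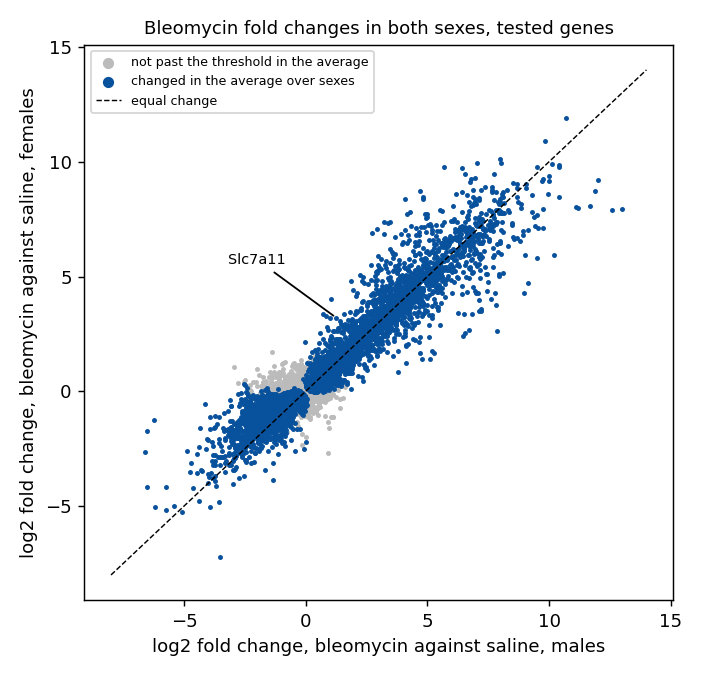
Fitted log2 fold change of each tested gene under bleomycin in males (horizontal axis) and females (vertical axis), with genes past the threshold in the average over the sexes in blue, the others in grey, and a dashed line of equal change. The points follow the line, with a Pearson r of 0.946 across genes, and Slc7a11 (named) lies above it; the fitted values of genes with almost no saline counts, at the far right, are no bounds.

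The test of the difference itself, the interaction of bleomycin with sex, called 1 gene. Slc7a11 (ENSMUSG00000027737, GRCm38 chromosome 3, 49892526 to 50443614) encodes the cystine transporter subunit xCT, which feeds glutathione synthesis. It rose from 10.8 ± 1.56 to 98.8 ± 18.9 CPM in females (3.20, SE 0.22) and from 38.7 ± 14.2 to 92.7 ± 13.5 CPM in males (1.26, SE 0.20), and the effect in males minus that in females was -1.93 (SE 0.29), with an edgeR adjusted p of 0.0436. The bleomycin levels of the sexes overlapped, and the saline levels differed. At an unadjusted p under 0.05 there were 1202 genes. The call of Slc7a11 did not hold under limma voom (adjusted p = 0.206). Its adjusted p ran from 1.06e-08 to 0.345 over the other settings and from 0.00354 to 0.183 with 1 library left out, where 4 of 16 fits still called it. None of the 31 lists was called (smallest camera adjusted p 0.413).

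Under saline, the sexes differed in 29 autosomal genes besides those of the sex chromosomes in the fit to all 16 libraries. The cystine transporter gene Slc7a11 was higher in males by 1.84 (SE 0.21), and the chaperone genes Hspa1a by 3.22 (SE 0.42) and Hspa1b by 2.58 (SE 0.36, 18.9 ± 7.96 against 3.17 ± 1.19 CPM). Also higher were the phagosomal metal transporter gene Slc11a1 by 2.21 (SE 0.31), the cholesterol efflux transporter gene Abca1 by 1.07 (SE 0.14, 296 ± 17.1 against 141 ± 28.5 CPM), Arl4c by 1.02 (SE 0.16), the stearoyl-CoA desaturase gene Scd1 by 0.63 (SE 0.12) and the dendritic cell lectin gene Clec9a by 0.73 (SE 0.14). Lower in males were the amino acid transporter gene Slc7a5 at -0.63 (SE 0.081, 61.7 ± 1.87 against 95.6 ± 7.32 CPM) and the cholesterol synthesis gene Sqle at -0.59 (SE 0.12). The CTP synthase gene Ctps stood at -0.59 (SE 0.10), St7 at -0.62 (SE 0.12) and Gca at -0.62 (SE 0.12). On the X chromosome Eif2s3x at -0.92 (SE 0.066), Ddx3x at -0.56 (SE 0.069), Kdm6a at -0.52 (SE 0.093) and the RNA-sensing receptor gene Tlr8 at -0.69 (SE 0.13) were lower in males. The edgeR adjusted p was 0.000207 for Slc7a11, 0.000552 for Abca1, 0.000591 for Slc7a5 and 0.0486 for Sqle, and in each of these genes all 4 male libraries lay on one side of all 4 female libraries.

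In total 41 genes differed between the sexes under saline at an edgeR adjusted p of 0.05, 22 higher and 19 lower in males. Of these 7 lay on the X chromosome, 5 on the Y chromosome and 29 on autosomes, and 1459 genes had an unadjusted p under 0.05. Of 20 cholesterol biosynthesis genes 2 were lower in males over all genes, and 14 adjusted over the list alone, with a camera adjusted p of 0.171 with an estimated correlation. Of 13 NRF2 genes 1 was higher in males, and 7 adjusted over the list alone, with a camera adjusted p of 0.38 with an estimated correlation. The lists of Y-linked genes (4 of 4 higher in males, adjusted over the list alone also 4) and of X-linked genes that escape inactivation (4 of 8 lower, 7 adjusted over the list alone) were called, with camera adjusted p of 3.1e-06 and 9.44e-06. The groups did not overlap in 13.1% of the genes, against 2.86% by chance. The count depended on the libraries in the fit: with the 8 saline libraries alone, where filter, scaling and spread are all set by these libraries, 765 of 13450 genes passed. With 1 library left out it ran from 20 (without C76) to 35 (without C74), with 21 without C72, 21 without C73, 23 without C77, 24 without C75 and 26 without C70.

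**Figure D4:**
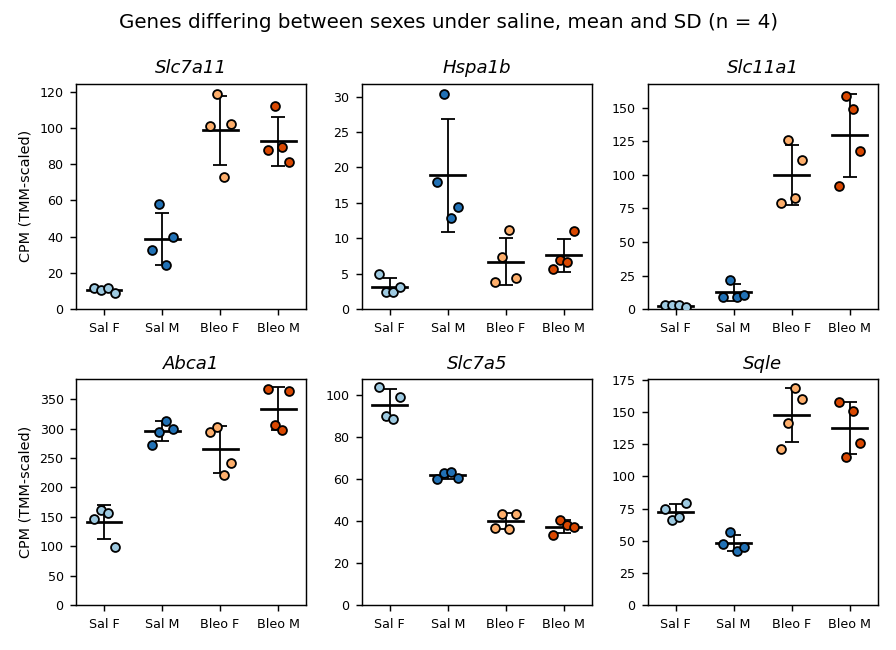
Composition-scaled CPM of 6 genes that differed between the sexes under saline, in each library (points), with the mean (long bar) and SD (error bars, n = 4) of the 4 groups on linear axes that start at 0. Slc7a11, Hspa1b, Slc11a1 and Abca1 were higher and Slc7a5 and Sqle lower in saline males than in saline females, while the bleomycin males and females overlap in all 6 genes.

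Under bleomycin, the sexes differed in genes of the sex chromosomes alone among the genes called. Besides the 4 Y-linked genes and Xist given above, the male-to-female difference was -0.77 (SE 0.093) for the histone demethylase gene Kdm6a (38.3 ± 2.39 against 65.4 ± 9.24 CPM), -0.67 (SE 0.09) for the demethylase gene Kdm5c (84.0 ± 10.9 against 134 ± 8.75 CPM) and -0.65 (SE 0.066) for the translation factor gene Eif2s3x. Their edgeR adjusted p was 0.000337, 0.00138 and 2.94e-05. In all 9 genes passed, 5 on the Y chromosome and 4 on the X chromosome, 0 were autosomal, and 605 genes had an unadjusted p under 0.05. DESeq2, limma voom and edgeR with DESeq2's size factors each called 9 genes as well. The groups did not overlap in 1.29% of the genes, where chance gives 2.86%. Both sex chromosome lists were called with an estimated correlation, the Y-linked genes (4 of 4 higher in males) with a camera adjusted p of 9.49e-08 and the X-linked escape genes (4 of 8 lower, 7 adjusted over the list alone) with 3.4e-06. Bleomycin itself raised 1 and lowered 1 of the 4 Y-linked genes in males, with changes from -0.459 to 0.232 (camera adjusted p = 0.421 with an estimated correlation). The average over the sexes called 0 of 4 (0.737), but females have almost no counts of these genes. In the average 1 of the 8 escape genes rose, Pbdc1 at 0.58 (SE 0.091), and 3 fell (6 without composition scaling), including Ddx3x at -0.22 (SE 0.049). The camera adjusted p of the escape genes was 0.275 with an estimated correlation. The T cell marker level was 4.71 ± 0.521 in bleomycin males and 4.37 ± 0.788 in bleomycin females, with an exact permutation p of 0.486.

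The count of 9 rested on libraries that did not behave alike. C33 (male), C49 and C50 (female) carry code numbers apart from the run of the others, and whether they mark another day or batch is not stated. Without them 670 genes differed between bleomycin males and females, 641 of them autosomal. Of 20 T cell markers 17, of 12 B cell markers 10 and of 10 NK markers 3 were then higher in males, and 10 of 20 resident alveolar macrophage markers lower. With the code run as a term in the model for all 16 libraries the count was 9. Long genes, of at least 5000 bases, took 38.85, 41.21 and 38.09% of the counts in C33, C49 and C50 and 33.42 to 36.11% in the other 5 bleomycin libraries, against 41.25 to 45.0% under saline.

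**Figure D5:**
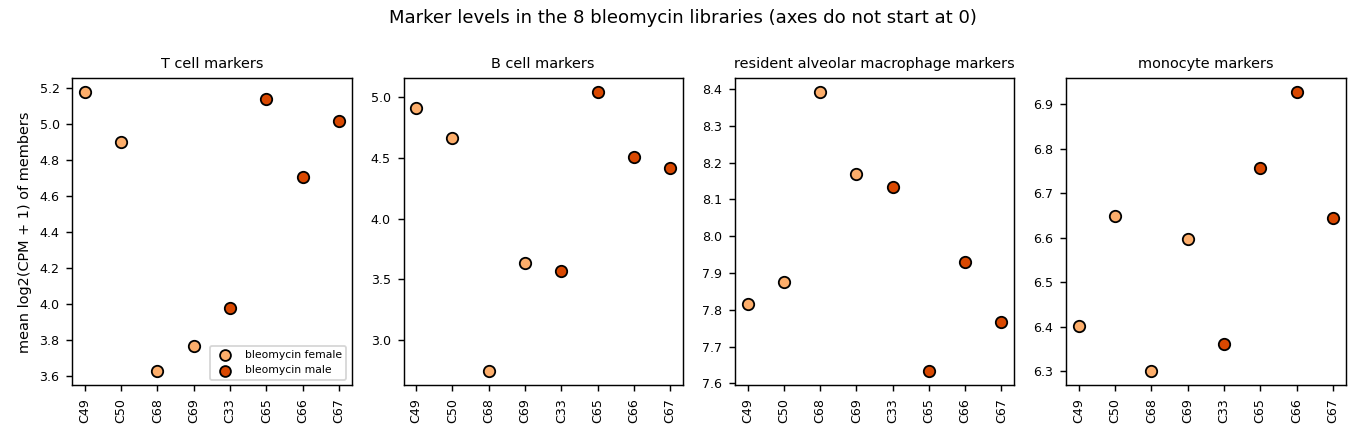
Mean log2(CPM + 1), with CPM by library total and no composition scaling, over the members of 4 marker lists in each bleomycin library. Females are in light and males in dark orange, and the axes do not start at 0. T cell and B cell markers were lowest in C68 and, for T cells, next lowest in C69 and C33, and the resident alveolar macrophage markers were highest in C68, and the ranges of the sexes overlap in all 4 lists.

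The authors' deposited tables of their own comparisons were set beside these counts. They list 9836 genes past an adjusted p of 0.05 for bleomycin in males, of which 8366 were also called here, 6651 in females (6011 shared) and 11430 for bleomycin over both sexes (9465 shared), and every shared gene had the same direction. The authors' deposited table for the sexes under bleomycin lists 10 genes, of which 9 were shared. For the sexes under saline the authors' deposited table lists 1214 genes, 569 higher and 645 lower in males, of which 38 were among the 41 called with all 16 libraries and 751 among the 765 called with the 8 saline libraries alone.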

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

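The tests on leaving out a saline library, on the scalings, on immediate early genes, on the code run and on T cell and other genes in C33, C49 and C50 were chosen after the results were seen, and the other splits of the libraries were planned. A library far from the other 3 of its group was found in 32 of the 570 groups of values examined, where chance alone gives about 1 in 20, or 28, so that no cause was sought for any single case.

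Saline male C71 accounts for 7 of these cases. In it the osteopontin gene Spp1 stood at 432.4 CPM (next library 311), Gapdh at 162.7 (12.93), the chemokine gene Ccl22 at 40.47 (24.32), Slc11a1 at 21.64 (10.71), Fscn1 at 19.86 (8.864), Hspa1a at 18.89 (8.945) and the fatty acid oxidation gene Acadvl at 43.9 (57.5). In other saline males Cidec stood at 378.7 CPM and Nlrp3 at 83.27 in C73, Cpne5 at 214 and Hk1 at 19.56 in C72, and the level of the eosinophil list was 0.04763 in C73 and 0 in the others. In saline females, Tlr8 stood at 394.1 CPM, C5ar1 at 342.9 and mt-Co3 at 54.2 (next 10.18) in C74, Mmp12 at 19.53 and the matrix protease list at 3.906 in C75, and Mcm7 at 69.55, Srxn1 at 41.9 and the Y-linked list at 0.03927 (from 2 counts of Ddx3y) in C76.

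In bleomycin males, C33 had 174.8 CPM of Bhlhe41 (next 203.4) and 16.59 of Fads2 (next 10.61), C65 had 16.36 of Me1 and C67 had 25.11 of Krt8. In bleomycin females, C68 had 384.8 CPM of Cpt1a, 181.1 of Lpin1 and 22.09 of the dendritic cell gene Flt3 (next 37.53), and C69 had 120.6 of Kdm5c, 69.71 of S100a8 (next 39.32) and a complement list level of 6.949 (next 6.639). C50 had 20.24 CPM of Csf1 and C49 13.8 of Clec9a. Between the sexes, the bleomycin effect on Slc7a11 differed by -1.93 in the test of the interaction.

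The first pattern weighed is the 29 autosomal genes that differed between the sexes under saline, among them Slc7a11, Slc11a1 and Abca1. Of the 35 splits of the saline libraries 1, the real one, reached 41 genes, of which those on X and Y follow from the sex labels. The highest other split called 0 genes on any chromosome, against 29 autosomal ones in the real split, so that chance is argued against. With 35 splits no stronger result than 1 of 35 can be had. With X and Y genes left out, 27 genes were called in the real split. Whichever saline library was left out, 29 of 29 kept their direction and most of their change. The genes were picked in these same libraries for a difference beyond their spread. Leaving out 1 library could therefore hardly change this, and it decides little about a single library as the cause. Of the 41 genes, 20 to 26 were still called with 1 library left out. The scaling is argued against as the whole cause, since at least 25 of the 29 stayed past the threshold under the other scalings. The TMM factors of the saline sexes also overlapped (1.062 to 1.098 in males, 1.053 to 1.095 in females). Stress on the cells from collecting the sexes in sequence cannot be told apart from sex. The labels give no order, and the codes of the saline males (C70 to C73) and saline females (C74 to C77) form separate runs. The median of 10 immediate early genes was -0.187 with members going both ways. This median left out Hspa1a and Hspa1b, the 2 members of the list of 12 that were called, both higher in males. The level of the whole list did not overlap between the saline sexes and was higher in males (exact permutation p = 0.0286, adjusted p = 0.111). A biological difference between the sexes was not tested and stays open.

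The second pattern is the 670 genes that differed between bleomycin males and females without C33, C49 and C50, 641 of them autosomal and 17 of them T cell markers. Among the 35 splits of the bleomycin libraries 4 called at least 9 genes, so that the size of that count alone does not exclude chance, though the 9 genes are 5 Y-linked and 4 X-linked and the list of Y-linked genes was called (camera adjusted p = 9.49e-08). The highest other split called 2703 when C33, C67, C49 and C50 were set against the rest, which points to a structure of the samples. It does not follow the code run alone, since C33, C49 and C50 called 1117 genes with C68 and 0 with C65, C66 or C69, and 288 were called with C33 apart from C49 and C50 (C33, C66, C68 and C69 against the rest). The T cell marker levels of the sexes overlapped: the lower of the 2 outside females had a level of 4.902 and the lowest of the 3 other males 4.706. This comparison was chosen after the results were seen, and the pattern itself arose by leaving out C33, C49 and C50. The overlap therefore decides nothing about a sex difference in the mean T cell marker level, which stays open. With the code run as a term, 35 of the 641 autosomal genes kept most of their change (9 genes called in all). This decides little about a shift shared by C33, C49 and C50 as the whole cause. The 641 genes were picked without these 3 libraries, and their calls ended once the 3 were in the fit. The T cell marker level was 3.979 in C33 against 5.178 and 4.902 in C49 and C50, so this level did not move together in the 3. A shared shift as part of the cause stays open. These 3 libraries stood apart from the other 5 in the share of rRNA (0.2735 to 0.366% against 0.429 to 0.6838%), of lincRNA (0.3842 to 0.6925% against 0.2483 to 0.2999%) and of the 10 most abundant genes (11.82 to 14.07% against 14.25 to 15.41%). They also stood apart in the TMM factor (0.9464 to 1.027 against 0.8633 to 0.9286) and on the second component (12.19 to 56.12 against -49.34 to 6.763). Lymphocyte content that varies between animals and a batch that moved these libraries in different directions cannot be told apart. Of the 432 autosomal genes higher in males in the other 5 libraries, 98.1% were higher in the mean of C49 and C50 than in C33, but their calls ended once the 3 libraries were in the fit, so that this value restates the pattern and supports neither.

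The third pattern is that bleomycin changed 1915 more genes in males than in females. With the sex labels drawn again within each treatment, 10 of 100 draws gave a difference as large and the highest other was 2586, so that chance cannot be excluded. Over all genes tested, the median size of the log2 fold change was 0.4481 in males and 0.3469 in females. The bleomycin females had the wider spread between libraries (median SD 0.178 against 0.137 in males). The groups share an estimate of the spread in the fit to all libraries, so this spread does not by itself lower the female count there. With only the 8 libraries of each comparison the counts were 8586 in males and 5646 in females. No biological explanation was tested for it.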

How the results depend on the processing

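The fits with the code run as a term and without composition scaling were chosen after the data were seen. The number of genes changed by bleomycin stayed within 1.5 times the reported count except under the strict filter (5725 in males, 6364 in the average), where fewer genes were tested, and the 2-fold criterion (3753 in males, 3033 in females, 3573 in the average). With 1 library left out the count ran from 7737 (C65) to 8927 (C33) in males, from 6067 (C75) to 7754 (C49) in females and from 9364 (C65) to 10487 (C49) in the average. Among the genes named for the average, 2698 of the values with 1 library left out kept their direction and side of the threshold, 2 came to pass and 1 ceased to pass.

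Between the sexes under saline the count of 41 became 191 with DESeq2, 119 without a filter, 765 with the 8 saline libraries alone, 277 without C33, C49 and C50, 96 with the code run as a term, 27 without X and Y genes, 19 at an adjusted p below 0.01 and 16 with the 2-fold criterion. With 1 library left out it ran from 20 (C76) to 35 (C74), with 21 without C72, 21 without C73, 23 without C77, 24 without C75 and 26 without C70. The fit to all 16 libraries shares 1 estimate of the spread over the groups. The median SD was 0.178 and 0.137 in bleomycin females and males against 0.093 and 0.0947 in saline females and males. The count of 41 can therefore be too low for the saline comparison, but the cause of the larger counts was not tested. Under bleomycin the count of 9 became 14 without a filter, 670 without C33, C49 and C50, and 0 without X and Y genes (edgeR, 570 at an unadjusted p under 0.05), and it ran from 8 to 10 with 1 library left out.

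The interaction rested on 1 gene. It became 23 genes with DESeq2, 15 without a filter and 77 without C33, C49 and C50. It became 0 with limma voom, 0 with the strict filter, 0 at an adjusted p below 0.01, 0 with limma on FPKM at either pseudocount, 0 with the code run as a term and 0 without composition scaling, with 895 to 1202 genes at an unadjusted p under 0.05 in these fits. With 1 library left out it was 0 or 1, and Slc7a11 was called without C65, C68, C71 or C72. The cause was not tested.

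Camera with the preset correlation called 20 lists in males, 24 in females, 24 in the average, 7 between the sexes under saline, 15 under bleomycin and 3 for the interaction. Fry called 27 in males, 27 in females and 28 in the average. Without C33, C49 and C50, camera with an estimated correlation called 0 lists in females and 6 between the sexes under bleomycin.

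Of the named genes, 3 changed direction. Without composition scaling Cd22 went to -0.0581 (adjusted p 0.372) and G6pdx to -0.0166 (adjusted p 0.796) in the average, where the median gene also moves to -0.20. The change of mt-Co3 in females did not pass with all libraries. Its change was 0.854 without C74 (adjusted p 0.00224) and -0.59 without C76, so that 1 saline library set its direction. Depth limits the genes with few counts in a group, whose fold changes are given as lower bounds or levels.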

Other observations

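The list levels between the sexes under saline and the tests of the bleomycin counts against other splits are given here, and both kinds of test were planned. Under saline, 6 lists besides those of the Y and X chromosomes had levels that did not overlap between the sexes (exact permutation p = 0.0286 for each, the smallest that 4 against 4 libraries can give, adjusted p = 0.111). The level of NRF2 antioxidant genes was 5.91 ± 0.221 in males and 5.39 ± 0.080 in females, and that of cholesterol biosynthesis genes 5.41 ± 0.077 and 5.75 ± 0.094. Mitochondrially encoded genes stood at 7.42 ± 0.059 in saline males and 7.62 ± 0.146 in saline females, and under bleomycin at 8.12 ± 0.045 and 7.93 ± 0.089, the opposite order (exact permutation p = 0.0286, adjusted p = 0.295). The saline difference of -0.201 was -0.13 without C74, whose level was 7.833, and -0.0877 with the median of the members. Resident alveolar macrophage markers were lower in males by a difference of -0.10 and fibroblast and endothelial markers higher by 0.14. The immediate early and heat shock list, 4.8 ± 0.073 in males and 4.52 ± 0.138 in females, had 2 of its 12 members called, Hspa1a and Hspa1b.

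For bleomycin in males, 8614 genes were called, and the highest of the 34 other splits of the 8 libraries called 0. In females the numbers were 6699 and 1. In each sex 1 of 35 splits reached the count, the fewest possible, which argues against chance. Each other split put bleomycin and saline libraries in the same group, which widens the spread within groups. Its low count is therefore no measure of how many genes chance alone calls. In the average 9700 genes were called, and the highest of the other splits, of which a draw was taken, called 5999. There 1 of 100 reached the count, which also argues against chance. The split with 5999 genes left the male libraries in their real groups and exchanged only the bleomycin female C69 and the saline female C76. It thus kept the treatment effect in males, where it called 7371 genes, and most females in their real group. Drawn splits that kept the males but exchanged more females called 6826 to 6925 genes in males and 0 in the average. For the interaction, where 1 gene was called, 6 of 100 splits called as many and the highest of the others 4, so that chance cannot be excluded.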
